A study of Gallus gallus with 3 samples.

How the data were processed

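Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on the neural tube of wild-type White Leghorn chicken embryos at stage HH30 of the Hamburger and Hamilton series, which stages the embryo by its form and not by hours of incubation. Eggs had been kept at 38.5 °C and 70% humidity, per the labels. Per the labels' protocols, dissociated cells were fixed in 1% formaldehyde for 10 min, chromatin was sheared by sonication, and fragments were recovered with an antibody against H3K4me3 (trimethylated lysine of histone H3, a mark of promoters in use or poised for use) or against H3K27me3 (a mark laid down by Polycomb repressive complexes over silent developmental genes). DNA that had not been immunoprecipitated was sequenced as the Input. The series held 3 samples, that is 1 library for each mark and 1 Input, so no replicate check of any value was possible and no p-value was computed. The labels do not say how many embryos went into a library.

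For each mark the authors deposited a list of peaks with the start, end and score of each. BWA, MACS2 and the chicken assembly galGal4 are named in the submitters' processing notes, without versions or parameters; per the file headers, peaks were called with MACS run in Galaxy. Whether the Input served as the control of the peak calls, and how reads were filtered, is not given in the sources used here. The deposited score is the peak caller's own value for the peak; its scale is not named in the files. Its range and the many peaks at exactly 3100, above which 154 H3K4me3 and 14 H3K27me3 peaks still lay, resemble the score of early MACS versions, a multiple of the negative log10 p-value, whereas the processing notes name MACS2. If so, the score measures significance, which rises with width and depth, and not enrichment; this was not settled. It ran from 50.01 to 3233.06 in the H3K4me3 list, and exactly 3100 was given to 1506 peaks of H3K4me3 (12.1%) and 469 peaks of H3K27me3 (7.48%), so that the scale did not rank many of the highest-scoring peaks. Scores were used within a list, to rank and divide peaks and to compare medians of sets of its peaks, and were related between lists only by rank (a rank correlation over overlapping pairs, and lists divided at their own medians). The lists hold no read counts: the depth of the libraries is unknown, and a place without a peak cannot be called free of the mark. The Input was not analysed here, since only peak lists were used.

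Peaks within a list did not overlap each other. A start below 0, found in 183 H3K4me3 peaks and 180 H3K27me3 peaks, none of them on an assembled chromosome, was set to 0. Coordinates are given counting from 1 on galGal4. No gene annotation of galGal4 was used here, because the gene table at hand describes another assembly and coordinates were not converted. Peaks were therefore not assigned to genes, exons or introns, and the planned comparisons of promoter classes, the 18 gene lists, HOX clusters and location relative to genes were not run. Chromosomes 1 to 5 were taken as macrochromosomes, 6 to 10 as intermediate chromosomes and 11 and above as microchromosomes; all sequences other than numbered chromosomes, Z and W were grouped as other sequences.

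Peaks of the 2 lists were called overlapping when they shared at least 1 bp. The count was set beside 10000 random placements of the H3K27me3 peaks, each keeping its width and chromosome, over the span from the chromosome's start to the last peak end in either list; the mean and the central 95% range of the placements are given as a description of these lists. Shares carry 95% Wilson intervals and differences between medians carry percentile intervals from 1000 bootstrap resamples of peaks. These intervals cover counting error only, treat neighbouring peaks as independent, and say nothing of the spread between embryos. The overlap count was tested on simulated data: with the H3K27me3 peaks placed at random the fold over random placement was 0.999, and with 500 of the 6267 peaks moved onto H3K4me3 peaks it was 2.25, with 458.5 peaks in excess. The simulated peaks were placed by the same rule as the random placements, so this checked the counting only. It did not test whether such placement suits these clustered lists. Regions were named by a rule set before the data were examined: the 5 widest peaks of each mark and the 5 longest overlaps. Domains were made by merging peaks of 1 mark that lay within 5 kb of each other, a step added after the data were examined. The division of peaks into score classes and 1 Mb windows, the crossing of the lists divided at their median scores and the densities per Mb of span were also chosen then. Alternatives covered the overlap rule (50% of the shorter peak, 10% of the peak, or within 1 kb), peaks at or above the median score, peaks at least as wide as the median, merging within 1 kb, assembled chromosomes only, and placement by circular shift or within 1 Mb; the overlap rules were compared with 200 placements. Calculations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.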

Results

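H3K4me3 and H3K27me3 were mapped by ChIP-seq in the neural tube of HH30 chicken embryos, with 1 library for each mark. At this stage the neural tube holds dividing progenitors and differentiating neurons of many kinds, so each list describes a mixture of cells. The peak lists held 12414 H3K4me3 peaks and 6267 H3K27me3 peaks. The read depth behind a peak is unknown, and all values below describe these libraries without replicates.

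The first question was how each mark was laid out along the genome. H3K4me3 formed many narrow peaks of similar size, whereas H3K27me3 formed fewer peaks that reached much greater widths. The median H3K4me3 peak was 1443 bp wide (quartiles 1071 and 1852 bp), and the median H3K27me3 peak was 1688 bp wide (quartiles 1057 and 2736 bp). Peaks wider than 5 kb made up 7.98% of the H3K27me3 list (500 peaks; 95% Wilson interval 7.33 to 8.68%) but 0.371% of the H3K4me3 list (46 peaks; interval 0.278 to 0.494%). The lists covered 19.2 Mb for H3K4me3 and 14.6 Mb for H3K27me3. Wider peaks had higher scores in both lists, with a Spearman correlation across peaks of 0.68 for H3K4me3 and 0.75 for H3K27me3; peaks are not independent replicates.

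**Figure D1:**
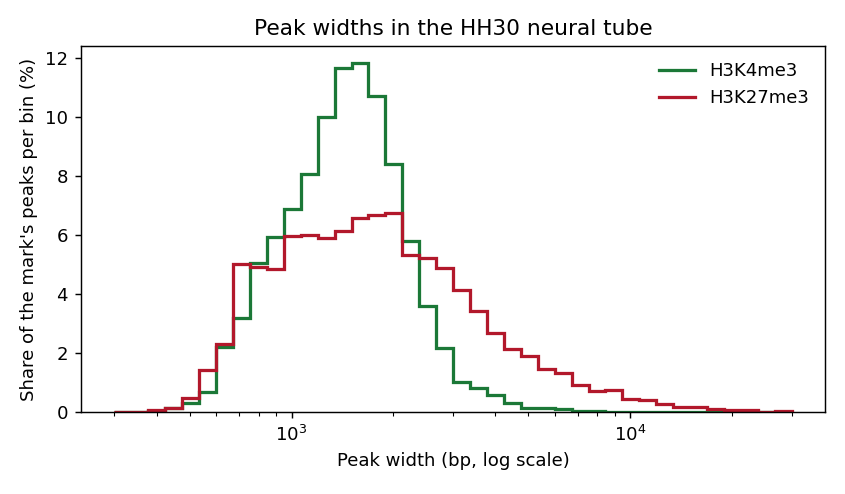
Share of each mark's peaks (y axis, % per bin) by peak width (x axis, bp, log scale) for the H3K4me3 list (green line) and the H3K27me3 list (red line), 1 library each. Both lists peak between 1 and 3 kb, with medians of 1443 and 1688 bp, and the H3K27me3 line continues past 10 kb, where the H3K4me3 list has 2 peaks and the H3K27me3 list has 95.

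Both marks were clustered, H3K27me3 more so. Another peak of the same mark lay within 5 kb of 57.5% of H3K27me3 peaks (95% Wilson interval 56.2 to 58.7%), against 11.3% when the same peaks were placed at random on their chromosomes (range 10.2 to 12.4%). For H3K4me3 the share was 35.6% (interval 34.8 to 36.5%), against 16.8% at random (range 15.9 to 17.6%). Merging peaks within 1 kb of each other gave 4578 H3K27me3 domains, of which 53 exceeded 20 kb and the longest reached 72458 bp, while none of the 10901 merged H3K4me3 regions exceeded 20 kb. With merging within 5 kb, 120 H3K27me3 and 8 H3K4me3 domains exceeded 20 kb.

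The widest H3K27me3 peaks were long blocks that held little or no H3K4me3. The widest lay on chromosome 8 from 19497300 to 19526496 (29.2 kb), followed by peaks on chromosome 17 from 6454727 to 6483794 (29.1 kb) and on chromosome 3 from 3284493 to 3313477 (29.0 kb). None of these overlapped an H3K4me3 peak, and the nearest lay 46.6, 9.41 and 61.9 kb away. The fourth, on chromosome 2 from 24561315 to 24584604 (23.3 kb), held 1 H3K4me3 peak over 5.19% of its length. These 4 peaks had the score of 3100 shared by many of the highest-scoring peaks. The fifth, near the end of chromosome Z from 81931259 to 81953521 (22.3 kb), had a score of only 55.73.

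The widest H3K4me3 peak spanned 14.2 kb on chromosome 7, from 15780947 to 15795153, and the second spanned 10.4 kb on chromosome 28, from 3373359 to 3383719. They were followed by peaks on chromosome 5 from 5226915 to 5235704 (8.79 kb), on chromosome Z from 60284729 to 60293136 (8.41 kb) and on chromosome 1 from 135630467 to 135638808 (8.34 kb). The relation to H3K27me3 differed among these 5 places. H3K27me3 covered the whole of the chromosome 5 peak. On chromosome 28 and chromosome 1 the nearest H3K27me3 peak was 43.9 and 59.1 kb away, and on Z it was 2.47 kb away. The chromosome 1 peak scored 98.33, while the other 4 scored above 3000. At the chromosome 7 site H3K27me3 covered 9.94% of the H3K4me3 peak, at the edge with the higher coordinate, and then ran on with few gaps to position 15846066, in 5 peaks that each scored 3100. H3K4me3 peaks continued into the first part of this H3K27me3 block, with scores between 54.42 and 741.86.

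**Figure D2:**
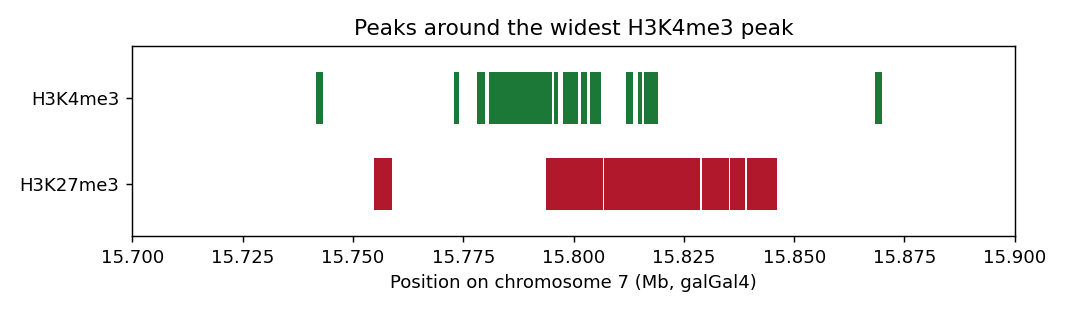
Peaks of H3K4me3 (upper row, green) and H3K27me3 (lower row, red) on chromosome 7 between 15.7 and 15.9 Mb of galGal4 (x axis, Mb), each bar drawn to the peak's start and end, 1 library per mark. The widest H3K4me3 peak (14.2 kb) overlaps the lower-coordinate edge of an H3K27me3 block that ends at 15846066.

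The comparison implied by profiling both marks in the same tissue is how often they occupied the same places. Most H3K4me3 peaks carried no H3K27me3 peak, yet the lists met far more often than random placement along the chromosomes gave. That placement took no account of promoters, base composition or assembly gaps, since neither annotation nor sequence was used. Of the H3K4me3 peaks, 2212 overlapped H3K27me3, which is 17.8% (95% Wilson interval 17.2 to 18.5%). Random placement of H3K27me3 gave 377.8 on average (range 340 to 416), a 5.86-fold difference, and no placement of 10000 exceeded 454. Of the H3K27me3 peaks, 2223 overlapped H3K4me3, or 35.5% (interval 34.3 to 36.7%), 6.19 times the random mean of 359.0. Placement within 1 Mb to either side of the true position, which keeps density only over regions longer than that span, gave 5.14-fold and 5.42-fold. When only peaks at or above the median score of their list were kept, the fold fell to 2.24 for H3K4me3 and 2.30 for H3K27me3.

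After the lists were joined, 10202 regions held H3K4me3 alone, 4044 held H3K27me3 alone and 2159 held both, the last being 13.2% of 16405 regions (95% Wilson interval 12.7 to 13.7%). Where the marks met, they shared most of the H3K4me3 peak. The median overlapping H3K4me3 peak was covered by H3K27me3 over 98.5% of its length (lower quartile 86.0%). Of these peaks, 810 lay wholly inside H3K27me3 (36.6%; interval 34.6 to 38.6%), whereas 254 of the overlapping H3K27me3 peaks lay wholly inside H3K4me3 (11.4%; interval 10.2 to 12.8%). A further 47 H3K27me3 peaks held at least 2 H3K4me3 peaks each, up to 6. Mapping of separate libraries from a mixed tissue does not show whether both marks lay on the same chromatin fragment.

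The longest stretch with both marks was the H3K4me3 peak on chromosome 5 from 5226915 to 5235704 (8.79 kb), which lay inside an H3K27me3 peak of 12485 bp. The second lay on chromosome 2 from 63367874 to 63375397 (7.52 kb), inside an H3K27me3 peak of 11986 bp. The third, of 6.22 kb, was on an unplaced scaffold, between its positions 19711 and 25928, with scores of 217.97 for H3K4me3 and 767.69 for H3K27me3. The next lay on chromosome 15 from 12567092 to 12572062 (4.97 kb) and on chromosome 14 from 2397383 to 2402013 (4.63 kb). At each of the 4 sites on assembled chromosomes H3K27me3 had a score of 3100, and H3K4me3 scored between 1902.25 and 3010.57.

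H3K4me3 peaks shared with H3K27me3 had lower scores than the others. The scale of the score is not named in the files, and a ratio of scores is not a ratio of enrichment. Their median score was 430.4 (quartiles 152.3 and 1044.6), against 1299.4 (quartiles 493.3 and 2401.1) for H3K4me3 peaks without H3K27me3, a ratio of 0.331 (95% bootstrap interval 0.307 to 0.359). Random placement gave a ratio of 1.04 (range 0.867 to 1.23). The overlapping peaks had the lower median score in 10 of 10 classes of equal number by width. The share of H3K4me3 peaks that overlapped H3K27me3 was 35.5% (95% Wilson interval 32.5 to 38.6%) for scores from 50 to 100 and 5.96% (interval 4.92 to 7.21%) for scores of 3100 and above. The median widths were 1435 bp with H3K27me3 and 1444 bp without, a difference of -9 bp (interval -43.5 to 27.5 bp). Random placement favoured wide peaks, with a difference of 115.5 bp (range 33.5 to 195.0 bp). Among peaks at or above the median score of their list the difference turned to 503 bp, the peaks with H3K27me3 being the wider, and after merging within 1 kb it was 44 bp. The widest 10% of H3K4me3 peaks, from 2331 bp upwards, overlapped H3K27me3 in 22.8% of cases (interval 20.5 to 25.2%), against 14.6 to 19.6% in the other 9 classes of equal number.

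H3K27me3 peaks shared with H3K4me3 scored higher and were wider in the median than those without. Their median score was 355.4, against 166.7 (a ratio of 2.13; 95% bootstrap interval 1.91 to 2.39), and their median width was 1925 bp, against 1522 bp (a difference of 403 bp; interval 327.5 to 477.1 bp). Wider H3K27me3 peaks meet H3K4me3 more often by chance, and score rose with width. No random value was computed for this ratio or this difference, so neither can be read as an excess over chance. The share overlapping H3K4me3 was 21.0% (95% Wilson interval 19.2 to 23.0%) for H3K27me3 scores below 100 and 48.0% (interval 45.3 to 50.6%) for scores from 300 to 1000. It stayed at 47.5% for scores from 1000 to 2000 and 45.1% for scores from 2000 to 3100, and was 27.5% (interval 23.7 to 31.7%) for scores of 3100 and above. The widest 10%, from 4463 bp upwards, overlapped in 28.9% of cases (interval 25.5 to 32.5%), and peaks of 2004 to 2444 bp in 49.1% (interval 45.2 to 53.0%). Among H3K27me3 peaks of like width, the score ratio of overlapping to other peaks was smaller than 2.13. Median scores were 75.6 and 62.7 in the narrowest of 10 classes of equal number. They were 770.5 and 495.0 at 2445 to 3100 bp, where the ratio was largest, and 3100 for both in the widest class. When each list was divided at its median score, the lower-scoring H3K4me3 peaks overlapped the higher-scoring H3K27me3 peaks 9.62 times as often as at random (1133 of 6207 peaks; interval 9.13 to 10.1) and the lower-scoring ones 7.95 times as often (564 of 6207; interval 7.35 to 8.60). The higher-scoring H3K4me3 peaks overlapped the higher-scoring H3K27me3 peaks 2.23 times as often (277 of 6207; interval 1.99 to 2.5) and the lower-scoring ones 3.72 times as often (268 of 6207; interval 3.30 to 4.18). The excess was thus larger for low-scoring H3K4me3 with either class of H3K27me3. Over the 2276 overlapping pairs of peaks, the scores of the marks had a Spearman correlation of -0.18.

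**Figure D3:**
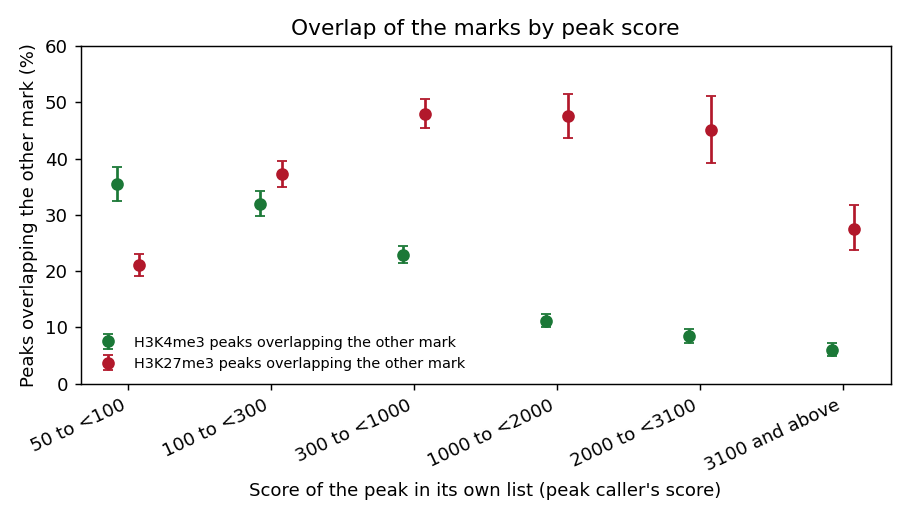
Percentage of peaks that overlap the other mark (y axis) by the peak's score in its own list (x axis, peak caller's score), for H3K4me3 peaks (green) and H3K27me3 peaks (red), 1 library each; bars are 95% Wilson intervals. The H3K4me3 points fall from 35.5% in the lowest class to 5.96% in the highest, and the H3K27me3 points rise from 21.0% to 48.0%, stay near that level below a score of 3100, and end at 27.5%.

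Most H3K27me3 peaks that did not overlap H3K4me3 lay more than 5 kb from it, yet more lay within 5 kb than in random placements. Of these 4044 peaks, 795 lay within 5 kb of H3K4me3, or 19.7% (95% Wilson interval 18.5 to 20.9%), against 11.3% in random placements (range 10.5 to 12.1%). Within 5 kb of an H3K4me3 peak, overlaps included, lay 3018 H3K27me3 peaks, or 48.2% (interval 46.9 to 49.4%), against 16.3% in random placements (range 15.5 to 17.2%). Among peaks at or above the median score of their list this was 15.8% (interval 14.6 to 17.1%), against 10.4% in random placements of those peaks (range 9.35 to 11.4%). The median distance of those without overlap was 23.8 kb (quartiles 6.72 and 59.5 kb), for which no random value was computed. This left out the sequences without H3K4me3, which held 299 H3K27me3 peaks.

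The chicken genome is divided into large macrochromosomes and small, gene-dense microchromosomes, and the peaks were compared between these classes. Both marks were denser on microchromosomes, and the difference was larger for H3K27me3. Microchromosomes held 3645 H3K4me3 peaks (29.4% of the list; 95% Wilson interval 28.6 to 30.2%) and 2009 H3K27me3 peaks (32.1%; interval 30.9 to 33.2%). Per Mb of span, from a chromosome's start to its last peak end, H3K4me3 had 21.3 peaks on microchromosomes and 9.43 on macrochromosomes, a ratio of 2.26. H3K27me3 had 11.7 and 4.03, a ratio of 2.91. The share of H3K27me3 peaks that overlapped H3K4me3 was 28.5% on microchromosomes (interval 26.5 to 30.5%) and 44.3% on macrochromosomes (interval 42.4 to 46.3%), while the share of H3K4me3 peaks that overlapped H3K27me3 was 15.8% (interval 14.6 to 17.0%) and 18.7% (interval 17.7 to 19.7%). Microchromosomes had 55.1 H3K27me3 peaks per 100 H3K4me3 peaks and macrochromosomes 42.7. Chance overlap would raise the first of these shares on microchromosomes, where H3K4me3 peaks covered 33.9 kb per Mb of span, against 14.4 on macrochromosomes. Random placement was not run by chromosome class. Chromosome Z, the sex chromosome present in both sexes of birds, held 608 H3K4me3 and 331 H3K27me3 peaks, and 19.4% of its H3K4me3 peaks overlapped H3K27me3 (interval 16.5 to 22.7%).

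Single chromosomes differed in the balance of the marks. Over all sequences there were 50.5 H3K27me3 peaks per 100 H3K4me3 peaks. Chromosome 25 had 16.3 (interval 9.51 to 28.0; 15 H3K27me3 and 92 H3K4me3 peaks), and chromosome 1 had 34.8 (interval 31.7 to 38.2). Chromosome 27 had 81.1 (interval 65.1 to 101.2), chromosome 24 had 77.3 (interval 59.5 to 100.5), chromosome 13 had 76.6 (interval 64.0 to 91.6) and chromosome 6 had 73.5 (interval 63.4 to 85.3). Chromosome 22 had 73.5 (interval 52.9 to 102.1), chromosome 20 had 66.2 (interval 55.2 to 79.4) and chromosome 23 had 65.4 (interval 51.9 to 82.3). On chromosome 27 the excess rested on its first Mb, which held 58 H3K27me3 and 6 H3K4me3 peaks; without it the chromosome had 49.7 (interval 38.3 to 64.5). Chromosome 22 rested on its window from 1 to 2 Mb, which held 39 H3K27me3 and 12 H3K4me3 peaks. Without that window it had 30.99 (interval 19.3 to 49.8), below the value over all sequences. Without the 1 Mb window with the most H3K27me3 peaks on each, chromosome 13 had 63.5 and chromosome 6 had 60.5. Chromosomes 20, 23 and 24 were not checked in this way. On chromosomes 25 and 28, 3.26% and 5.68% of H3K4me3 peaks overlapped H3K27me3 (intervals 1.12 to 9.15% and 3.12 to 10.1%), compared with 23.8% on chromosome 6 (interval 19.9 to 28.1%). These intervals were not corrected for the 30 chromosomes compared.

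**Figure D4:**
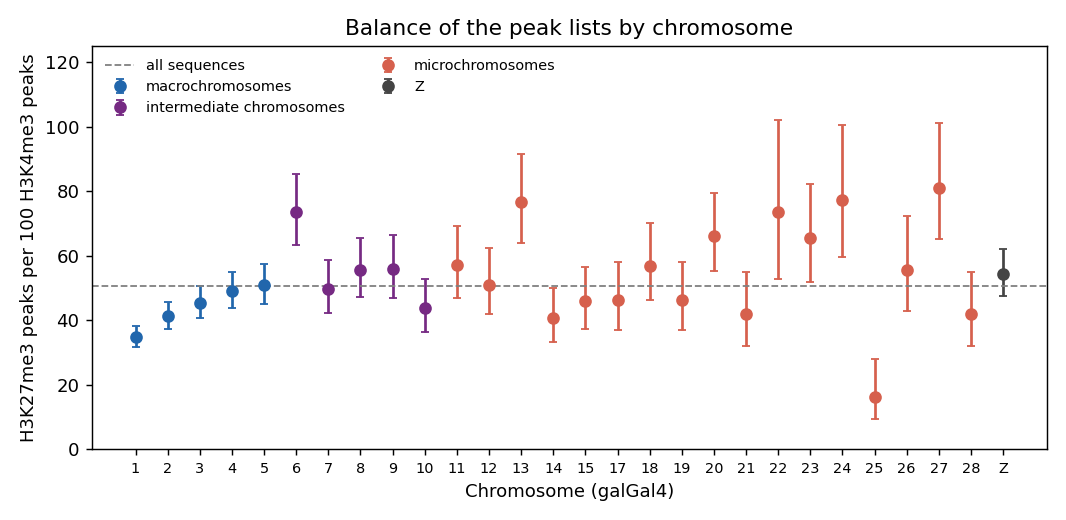
H3K27me3 peaks per 100 H3K4me3 peaks (y axis) on each chromosome with at least 50 H3K4me3 peaks (x axis), coloured by chromosome class; bars are 95% Wilson intervals turned into ratios, and the dashed line is the value over all sequences (50.5). Chromosome 25 (16.3) and chromosome 1 (34.8) are among those below the line. Chromosomes 6, 13, 20, 22, 23, 24 and 27 are among those above it. Chromosome 27 is above it through its first Mb, without which it has 49.7. Chromosome 22 is above it through its window from 1 to 2 Mb, without which it has 30.99.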

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

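The overlap of the marks stayed above random placement under every alternative run, and it was smallest when low-scoring peaks of both lists were left out. In pairs for H3K4me3 and H3K27me3 peaks, the share overlapping was 17.8 and 35.5%, and the fold over random 5.86 and 6.19. With an overlap of 50% of the shorter peak these were 17.1 and 33.9%, and 7.99-fold and 8.31-fold; with 10% of the peak the folds were 6.24 and 6.90. Counting peaks within 1 kb as shared gave 19.9 and 40.4%, and 4.51-fold and 4.98-fold. Peaks at or above the median score of their list gave 4.46 and 9.09%, and 2.24-fold and 2.30-fold; that setting by construction keeps 6207 and 3134 peaks. Peaks at least as wide as the median gave 13.3 and 26.1%, and 5.56-fold and 5.52-fold. Merging within 1 kb gave 18.5 and 43.4%, and 6.24-fold for H3K4me3. Assembled chromosomes alone gave 37.2% for H3K27me3, and 6.34-fold and 6.80-fold. Circular shifts gave 6.23-fold for H3K4me3, and placement within 1 Mb 5.14-fold and 5.42-fold. The difference in median H3K4me3 width of -9 bp became 503 bp above the median scores and 44 bp after merging, the first among high-scoring peaks alone. The score ratio of 0.331 became 0.390 without peaks at the top of the scale. Median widths (H3K4me3, H3K27me3) were 1649 and 2064.5 bp after merging within 1 kb, 1735 and 2281 bp within 5 kb (leaving 3777 H3K27me3 regions), 1752 and 2600.0 bp above the median scores, and 1458 and 1747 bp on assembled chromosomes. By covered length, microchromosomes held 30.2% of H3K4me3 and 35.6% of H3K27me3. Leaving out the 10 windows with the most H3K27me3 peaks brought H3K27me3 peaks per 100 H3K4me3 peaks from 81.1 to 38.8 on chromosome 27 (49.7 without its window from 0 to 1 Mb alone, 84.4 without that from 4 to 5 Mb), from 73.5 to 30.99 on chromosome 22 and from 57.0 to 34.5 on chromosome 11. The share of H3K27me3 within 5 kb of H3K4me3 was 44.4% between midpoints and 15.8% above the median scores, where random placement gave 10.4%. Merging within 5 kb, assembled chromosomes for widths and scores, the removal of top scores and the leaving out of windows were chosen after the data were seen. Apart from settings that by construction keep fewer or longer peaks, the cause was not tested. With no read counts, low and absent enrichment cannot be separated, and the top of the score scale does not rank peaks. No paired analysis was possible because each mark had 1 library. All alternatives that need genes (promoter window, transcript start, matched random lists, cluster flanks, location of peaks) were not run, as no annotation of galGal4 was used.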

Other observations

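The domains, windows and wide low-score peaks below were chosen after the data were seen, and so were the test of antibody recovery and the separate tests of 3 windows on chromosomes 3 and 5; the tests of regional density and of split domains were set before their results were seen.

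Merging peaks within 5 kb of each other brought out a few very long stretches of each mark. The longest H3K4me3 stretch ran over 73.5 kb of chromosome 27, from 3567388 to 3640934, and held 22 H3K4me3 peaks over 67.8% of its length and 0 H3K27me3 peaks. The second, on chromosome 7 from 15772923 to 15806209 (33.3 kb), ran into H3K27me3 over 37.5% of its length. The third, on chromosome 9 from 11380828 to 11408277 (27.4 kb), was covered by H3K27me3 over 83.2% of its length. The longest H3K27me3 stretch covered 109.7 kb of chromosome 9, from 12393091 to 12502835, with 25 H3K27me3 peaks and 1 H3K4me3 peak. A pair of H3K27me3 stretches of 79.3 and 77.2 kb lay on chromosome 2, from 32974074 to 33053396 and from 33156216 to 33233378. The distance between them was longer than either, and they held 3 and 2 H3K4me3 peaks. H3K4me3 was present in 45.8% of the 120 H3K27me3 domains longer than 20 kb (95% Wilson interval 37.2 to 54.7%), in 40.4% of those of 10 to 20 kb, in 40.5% of those of 5 to 10 kb, in 66.5% of those of 2 to 5 kb (interval 63.9 to 69.1%) and in 45.3% of shorter ones. Longer domains meet H3K4me3 more often by chance. Domains were not placed at random, so like shares at unlike lengths do not mean a like excess.

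The lower scores of H3K4me3 peaks that overlapped H3K27me3 (a ratio of medians of 0.331) were set against 2 technical explanations. Regions where H3K4me3 scores are low might hold more H3K27me3. Placing H3K27me3 within 1 Mb of its true position gave a mean ratio of 0.988 (range 0.815 to 1.17). This argues against density as the cause only over regions longer than the whole span of 1 Mb to either side. Variation over shorter distances, such as the length of H3K27me3 domains, is not kept by that placement and was not tested. Recovery of H3K27me3 chromatin by the H3K4me3 antibody stays open. Overlapping H3K27me3 peaks scored 2.13 times higher in the median, and the share overlapping rose from 21.0 to 48.0% with H3K27me3 score. Both go with recovery, but score also rose with width, and among peaks of like width the score ratio was smaller. The share of 27.5% for scores of 3100 and above, most of them at exactly 3100, does not go with recovery. Nor does the Spearman correlation between the scores of the marks over overlapping pairs, which was -0.18. It was -0.14 among pairs with both scores below 3100. The design has 1 tissue and 1 stage, so no biological explanation was tested: low H3K4me3 at H3K27me3-marked places in every cell and full H3K4me3 in a minority of cells stay open.

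H3K27me3 peaks piled up in a few 1 Mb windows. The window from 18 to 19 Mb of chromosome 11 held 74 H3K27me3 peaks, that from 3 to 4 Mb of chromosome 3 held 62, and that from 34 to 35 Mb of chromosome 6 held 61, against a median of 4 over the 880 windows of assembled chromosomes with any. The 10 windows with the most peaks held 511 H3K27me3 and 182 H3K4me3 peaks. Of these H3K4me3 peaks, 53 overlapped H3K27me3 (29.1%; 95% Wilson interval 23.0 to 36.1%), against 17.7% elsewhere (interval 17.0 to 18.3%). Seen from H3K27me3, 54 of 511 peaks overlapped H3K4me3 (10.6%; interval 8.19 to 13.5%), against 37.7% elsewhere (interval 36.4 to 38.9%). Picking windows for many H3K27me3 peaks by itself raises the first share. The second share was low where there were 280.8 H3K27me3 peaks per 100 H3K4me3 peaks, against 47.1 elsewhere. Under random placement the second share would depend on H3K4me3 density and not on the number of H3K27me3 peaks. The lists did not meet at random, however. Over all sequences, 2276 overlapping pairs held 2223 H3K27me3 peaks, so 182 H3K4me3 peaks could meet only part of 511 H3K27me3 peaks. Picking windows for many H3K27me3 peaks can therefore lower the second share by itself. No placement was run for these windows. The window from 4 to 5 Mb of chromosome 27 had 15 of 39 overlapping (38.5%); without it the share was 8.26% (interval 6.10 to 11.1%). Broad domains split by the peak caller could give such counts, but 7 of the 10 windows were still among the 20 with the most domains after merging within 5 kb, which argues against it as the whole cause for those. Merging still cut the count from 74 to 17 in the window of chromosome 11 and from 58 to 41 in the first Mb of chromosome 27. The windows of chromosomes 18 and 22 stood at rank 19, with 13 domains each. Of the other 3, the windows from 3 to 4 Mb of chromosome 3 and from 35 to 36 Mb of chromosome 5 kept 12 domains each, against a median of 3 and a 95th percentile of 11 over all windows, which argues against it there too, by a small margin over a limit chosen afterwards. In the window from 2 to 3 Mb of chromosome 5, 39 peaks fell into 3 domains after merging within 5 kb but into 12 within 1 kb, and whether splitting made that count cannot be told.

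Wide H3K27me3 peaks with low scores gathered at the end of chromosome Z. Of 500 H3K27me3 peaks of at least 5 kb, 18 scored below 300, and 7 of these lay in the last 500 kb of the chromosome's span, between 81911329 and 82311932, with widths of 6.38 to 22.3 kb. Of the 18, 0 overlapped an H3K4me3 peak, which at 3 counts of 18 allows a share of up to 16.7% (95% Wilson upper bound 17.6%), against 26.8% of all H3K27me3 peaks as wide; neighbouring peaks are not independent, and enrichment below the limit of the peak calls would not appear. No explanation was tested, since neither sequence nor read depth was used here.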
